A study of Mus musculus with 9 samples.

How the data were processed

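RNA from mouse colon organoids (epithelial mini-organs grown in culture from colon) was hybridised to 9 Agilent single-colour (Cy3) whole-genome arrays, 3 from cultures at 0 weeks, 3 after 12 weeks and 3 after 60 weeks of treatment with inflammatory reagents. Per the file headers, the authors scanned and quantified the arrays with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, and the array design refers to build mm9:NCBI37:Jul2007. The deposited scanner files hold an intensity for each spot: a background-subtracted, spatially detrended value on a linear scale that was not scaled between arrays. The deposited value table holds a signal for 42530 of the 55681 non-control probes. The table's source description was not used here; its values are the intensities divided by 1 constant per array, which lies at 0.992 to 0.996 of that array's 75th percentile, on a linear scale. The medians of the table's columns are 0.0668, 0.0719 and 0.0705 at 0 weeks, 0.0619, 0.0681 and 0.0733 at 12 weeks, and 0.0673, 0.0695 and 0.0582 at 60 weeks. All columns were matched to a sample, with 0 left over.

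The scanner files were used, since they hold every probe with its quality calls. Spots called non-uniform or population outliers were treated as missing (117 to 163 of 59305 non-control spots per array), the spots of a probe were averaged, and log2 values were taken relative to each array's 75th percentile over non-control probes. A value of 0 therefore stands for a probe as bright as that percentile. No spot was saturated (0 on every array). Probes were kept when the scanner software called them well above background on at least 2 of the 3 arrays of at least 1 group. The scanner files carry no gene symbols, so probes were named through their RefSeq accession in a table of the GRCm38.p6 annotation, which also gave chromosomes and neighbouring genes. Of the probes, 27235 had a symbol, 0 had several and 28446 had none. Each gene was represented by its probe with the highest mean over the 9 arrays. This gave 14013 tested genes out of 20660 named on the array, and 4460 of the tested genes had several probes. Among 3636 genes with several probes above background, probes of the same gene were called in opposite directions for 46 genes at 12 against 0 weeks, 18 at 60 against 0 weeks and 48 at 60 against 12 weeks.

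Group means were fitted over all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a block for the replicate numbers, and the 3 comparisons were tested two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. limma's moderated F test asked whether a gene differed among the 3 groups. Gene lists for pathways, epithelial cell types, other cell types and cell states (40 lists, of which 39 had at least 3 measured members) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 117 tests, and once more with the correlation estimated from the data. Comparisons, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 10 largest rises and the 10 largest falls among called genes whose 3 arrays of 1 group all lie beyond the 3 of the other and whose symbol is not a clone or predicted-gene name; up to 4 members per described list in order of adjusted p; and a fixed panel of stem cell, differentiation, inflammation, proliferation and epithelial genes. A gene whose probe was not well above background on any array of a group has no measured fold change. Its change is given as "at least N-fold", computed with each array of that group set to the lowest value called well above background on that array, or to the gene's own value where that was higher, and the order among such genes carries no meaning. List medians are also given with such members at their bound where this moves the second decimal.

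In data simulated with the fitted spread of each gene, 67 genes were changed by log2 0.5, 67 by 1 and 66 by 2. The 12 against 0 weeks fit recovered 4.48%, 64.2% and 89.4% of them, the 60 against 0 weeks fit 10.4%, 73.1% and 97.0%, and the 60 against 12 weeks fit 14.9%, 71.6% and 92.4%, with 5, 10 and 7 unchanged genes called. With no gene changed, limma called 0 genes in each comparison, and 715, 677 and 688 genes had an unadjusted p under 0.05. The noise was drawn independently for each gene with equal spread on all 9 arrays, as limma assumes. The real 12 weeks arrays spread more widely (median SD 0.21, against 0.11 at 0 weeks), so these rates need not hold for them. The overlap of the comparisons against 0 weeks was set against 20 simulations of 9 arrays without group differences, so that the shared 0 weeks arrays were carried into the expectation, and against 20 more in which the fitted changes of each comparison were shuffled among genes of like level.

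Precision is limited by the number of arrays, 3 per group. Between 49.2% and 52.7% of the probes were well above background per array, the 75th percentile lay 99.3 to 150 times above the negative controls, and the slope of the spiked-in RNA dilution series was 0.933 to 1.04. The 0 weeks arrays and replicate 1 of 12 weeks share a row of the first slide, replicates 2 and 3 of 12 weeks and replicates 1 and 2 of 60 weeks share its second row, and replicate 3 of 60 weeks is on another slide. The comparison of 60 with 0 weeks has no array of both groups in the same row.

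Alternatives changed 1 choice at a time: the background correction (normexp with offset 50 on the spots' median intensities, because the mean intensities are not in the files), the scaling between arrays (quantile, median, or a percentile over bright probes), the filter on dim probes, the outlier spots, the probe or mean that represents a gene, the deposited value table in place of the scanner intensities, the variance model, blocks for replicate number, slide or slide row, the arrays in the fit, each array left out in turn, a 2-fold requirement, and for lists the estimated correlation and the removal of shared genes. After seeing the data, 2 more were added: including features without a symbol, and leaving out genes on chromosomes 4, 5, 10, 12, 14, 19 and Y. With the slide row as a block, the change at 12 against 0 weeks rests on replicate 1 of 12 weeks alone. The change at 60 against 0 weeks then takes in the difference of that array from replicates 2 and 3 of 12 weeks. Replicate 3 of 60 weeks, alone in its row, does not contribute. A call that ends with this block therefore need not depend on the row. Replicate 3 of 60 weeks is also alone on its slide. The slide block and leaving out that array thus give the same fit, and both are counted among the alternatives.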

Results

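Gene expression was measured in mouse colon organoids in 3 groups of 3 arrays: before treatment (0 weeks), and after 12 and 60 weeks of treatment with reagents that the labels call inflammatory and do not name. The labels do not say whether the 3 replicates come from separate animals or cultures. There is no untreated culture at 12 or 60 weeks, so the treatment and the time in culture cannot be told apart in any comparison. Between 49.2% and 52.7% of the non-control probes were well above background per array, and 14013 genes were tested. Levels are log2 signals relative to the array's 75th percentile, with mean ± SD over n = 3 arrays, and changes are log2 fold changes ± SE with limma's adjusted p.

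Replicates of 0 weeks correlated at 0.994 to 0.996 across genes and those of 60 weeks at 0.990 to 0.994; genes are not independent replicates. At 12 weeks, replicates 1 and 3 correlated at 0.992, and replicate 2 at 0.978 and 0.977 with them. The median SD of a gene was 0.11 at 0 weeks, 0.21 at 12 weeks (0.10 without replicate 2) and 0.15 at 60 weeks. By limma's F test, 7944 genes (56.7%) differed among the 3 groups.

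The comparison of 12 with 0 weeks asks what changed in the first treatment period. After 12 weeks, 15 of 30 chemokine and cytokine genes and 13 of 21 defence genes were higher, list calls that ended with an estimated correlation (adjusted p = 0.597 each). Cxcl5, a chemokine that attracts neutrophils, rose by 6.76 ± 0.23 (adjusted p = 5.24e-07), from 1.46 ± 0.13 to 8.22 ± 0.51. S100a9, a subunit of the antimicrobial protein calprotectin, was not above background on any 0 weeks array and was at least 1813-fold higher at 12 weeks. Cdkn2a and Cdkn2b, adjacent genes on chromosome 4 that encode inhibitors of cyclin-dependent kinases, were at background at 0 weeks and at least 152-fold and 185-fold higher.

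Of 34 measured NF-kB targets, 17 rose and 3 fell at 12 weeks (20 adjusted over the list alone), with a median of 0.62 (camera, adjusted p = 4.45e-05; adjusted p = 0.597 with an estimated correlation). Of its feedback inhibitors, Nfkbia rose from 5.17 ± 0.10 to 6.18 ± 0.30 (adjusted p = 0.00121) and Tnfaip3 by 1.73 ± 0.18, and Ptgs2, which makes prostaglandins, rose by 3.44 ± 0.16. The chemokines Cxcl2 and Ccl2 were at least 23.6-fold and 42.8-fold higher, and Cxcl1 rose by 2.38 ± 0.29 (adjusted p = 0.000439). Among 30 chemokines, cytokines and receptors, of which 10 are also in other lists, 15 rose and 1 fell (17 adjusted over the list alone), with a median of 0.79 (adjusted p = 7.57e-05, and 0.597 with an estimated correlation). Csf2, a growth factor for granulocytes and macrophages, rose by 5.15 ± 0.34, and Cxcl3 was at least 19.8-fold higher. With the deposited value table, which lacks part of the probes, this list's call ended at a median of 0.29 (adjusted p = 0.0921; highest of its alternatives 0.597). In replicate 2 of 12 weeks, NF-kB targets deviated from replicates 1 and 3 by a median of -0.38 and the chemokine list by -0.41, both at percentile 0 of random lists of like level.

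Of 21 antimicrobial and epithelial defence genes, 13 rose and 1 fell at 12 weeks (15 adjusted over the list alone), with a median of 2.57, or 1.73 with members at their bound (adjusted p = 5.32e-05, and 0.597 with an estimated correlation). Replicate 2 deviated from replicates 1 and 3 by a median of -0.88 for these genes (percentile 0). Lcn2, which binds bacterial iron carriers, rose by 5.20 ± 0.51 from -0.70 ± 0.82 to 4.50 ± 0.92. Duoxa2, the maturation factor of a peroxide-generating oxidase, and Itln1, a lectin of goblet and Paneth cells, were at least 287-fold and 219-fold higher. Saa3, an acute-phase protein, was at least 221-fold higher and spread widely (3.05 ± 4.37), with 5.58 and 5.56 in replicates 1 and 3 and replicate 2 below 0. Reg3g was at least 1.80-fold higher and above background on 2 of 3 arrays, a call that ended with normexp background correction (0.51, adjusted p = 0.0660).

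Markers of mature colon cells also stood higher at 12 weeks, with wide spread between replicates for some, such as Slc5a8 and Car1. Of 17 goblet cell markers 10 rose and 0 fell (11 adjusted over the list alone), with a median of 1.66 (adjusted p = 0.00319, and 0.597 with an estimated correlation). The mucin gene Muc13 rose by 3.85 ± 0.20 and Galnt12, an enzyme that starts mucin sugar chains, by 2.30 ± 0.15. Creb3l4 rose by 1.63 ± 0.13, and Sytl2 was at least 5.08-fold higher. Of 31 colonocyte markers 17 rose and 5 fell (22 adjusted over the list alone), with a median of 1.04, or 0.79 with members at their bound (adjusted p = 0.0117, and 0.705 with an estimated correlation). For colonocyte markers, replicate 2 of 12 weeks deviated from replicates 1 and 3 by a median of -0.89 (percentile 0 of random lists of like level). For goblet cell markers it deviated by 0.39 (percentile 99.2). Slc5a8, a transporter of short-chain fatty acids, was at least 64.0-fold higher. Cdhr5 and Ceacam20, proteins of the brush border, rose by 1.80 ± 0.15 and 2.44 ± 0.28, while B4galnt2, above background on only 1 of 3 arrays at 12 weeks, fell by 3.74 ± 0.34. The colonocyte call ended with the deposited value table (median 0.21, adjusted p = 0.442) and without the 12 genes that other lists hold (1.80, adjusted p = 0.0526), within a range of 0.000279 to 0.705.

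The differentiation markers Krt20 and Car1 rose by 1.98 ± 0.57 (adjusted p = 0.0236) and 4.03 ± 1.16 (adjusted p = 0.0240). In replicate 2 they lay at 2.59 and 2.37, near the 0 weeks means of 2.18 and 1.37, against 4.70 and 6.42 in replicate 1 and 5.18 and 7.40 in replicate 3. Both calls ended without replicate 1 of 12 weeks (adjusted p = 0.0787 and 0.0792), replicate 3 of 12 weeks (0.0686 and 0.0722) or replicate 3 of 0 weeks (0.0718 and 0.0830), and Krt20's also without replicate 1 or 2 of 0 weeks (0.0525 and 0.0611). Both also ended with only the 2 groups compared (0.0569 and 0.0588) and with the row of the slide as a block, at 2.53 and 5.06 (0.0701 and 0.0763). Lgr5, a stem cell marker, fell by 2.01 ± 0.65 (adjusted p = 0.0372), with -1.72, 1.43 and -0.13 in the 3 replicates. Its call ended in 11 of 23 alternatives (adjusted p up to 0.0926), among them leaving out any single array except replicate 2 of 12 weeks, and the change was -1.22 without replicate 1 of 12 weeks. The slide block, also among the 11, repeats the fit without replicate 3 of 60 weeks. Of 22 stem cell markers 8 rose and 2 fell (10 adjusted over the list alone), with a median of 0.26 and no call (adjusted p = 0.261). Ascl2 was at least 5.54-fold higher, and Clca4b, Slc12a2 and Tert rose by 4.32 ± 0.55, 0.86 ± 0.13 and 1.06 ± 0.17.

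Senescence and secretory genes stood higher as a list (28 measured, 14 up and 5 down, 19 adjusted over the list alone; median 0.51, or 0.30 with members at their bound; adjusted p = 0.00994, and 0.597 with an estimated correlation). They include Cdkn2a, Cdkn2b, Cxcl2 and Igfbp7, the last at least 1.35-fold higher. This call ended with probes above background on all 9 arrays (0.03, adjusted p = 0.588), with the deposited value table (0.06, 0.305), without the 14 genes of other lists (0.12, 0.659) and without the chromosomes whose genes were shifted as a whole, described after the comparisons (0.07, 0.347). Of 46 DNA replication genes, 2 rose and 19 fell (22 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.00994, and 0.919 with an estimated correlation). The replication factors Rfc4, Orc6 and Dtl changed by -0.82 ± 0.10, -0.88 ± 0.11 and -1.06 ± 0.15, while the cyclin gene Ccne1 rose by 1.46 ± 0.10. Without replicate 2 of 12 weeks this list's call ended (-0.28, adjusted p = 0.0776). Of 61 nuclear genes of oxidative phosphorylation, 3 rose and 23 fell (28 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.00607, and 0.953 with an estimated correlation). Ndufa6, Atp5c1 and Ndufb10 changed by -1.07 ± 0.13, -0.64 ± 0.11 and -0.66 ± 0.13 and Uqcrq rose by 0.63 ± 0.10; quantile normalization ended the call (-0.11, adjusted p = 0.407). Of 38 interferon-stimulated genes 7 rose and 3 fell (9 adjusted over the list alone), with a median of 0.39 that did not pass (adjusted p = 0.149). It passed without replicate 2 of 12 weeks (0.73, adjusted p = 0.0125) and without replicate 3 of 0 weeks (0.56, 0.0295). Oas1a and Gbp2 rose by 6.10 ± 0.50 and 2.27 ± 0.49, Rsad2 was at least 2.42-fold higher and Isg20 fell by 1.95 ± 0.20.

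Among the largest rises at 12 weeks were Nts, which encodes the gut peptide neurotensin (at least 2216-fold), the prolactin-family gene Prl2a1 (at least 685-fold), Decr1 (at least 360-fold by this probe, a log2 fold change of 2.56 by its other probe), the signalling ligand Dhh (at least 166-fold) and the lactate transporter Slc16a3, which rose from -3.37 ± 0.16 to 5.63 ± 0.62 (adjusted p = 4.40e-07). The largest falls were Tmprss11c, Khdc1a and Megf6 (at least 93.5-fold, 65.2-fold and 33.0-fold lower), Adgra1, which went from -0.52 ± 0.22 to background on all 3 arrays, and Serpinb7, Foxo6, Gzmm, Ces2a, Zfp467 and Spp1, with changes of -5.99 to -5.10, of which Foxo6 was above background on only 1 array at 12 weeks. The size of the fall of Zfp467 depended on the processing, with -6.03 to -1.68 over its alternatives, while its call held in each. Spp1, which encodes osteopontin, went from 2.69 ± 0.11 to -2.41 ± 1.19. The panel genes Ly6a (-0.16 ± 0.15, adjusted p = 0.427), Mki67 (-0.03 ± 0.17, 0.915), Cdkn1a (-0.21 ± 0.16, 0.300), Myc (0.24 ± 0.18, 0.315), Cdh1 (0.27 ± 0.10, 0.0568) and Epcam (-0.28 ± 0.12, 0.0873) did not pass. Without replicate 2 of 12 weeks, Ly6a (-0.35, adjusted p = 0.00808) and Myc (0.42, 0.0324) passed, Cdh1 passed in 4 of 25 alternatives (lowest adjusted p = 0.0285), and Epcam passed without replicate 2 of 60 weeks (-0.28, 0.0432). Of the other panel genes, Olfm4 and Muc2 had no named probe, and Tff3, Chga and Slc26a3 were too dim to be tested.

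In all, 5852 of 14013 genes (41.8%) were called at 12 against 0 weeks, 2672 higher and 3180 lower, and 2070 of them by at least 2-fold. The groups did not overlap for 7647 genes (54.6%, against 10% by chance). Without replicate 2 of 12 weeks, 7394 genes were called. With the row of the slide as a block, 4467 were called. The balance of directions depended on the choices: 1190 higher and 880 lower among the 2-fold changes, 2989 and 2899 with the percentile over bright probes, and 3010 and 2982 with quantile normalization.

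**Figure D1:**
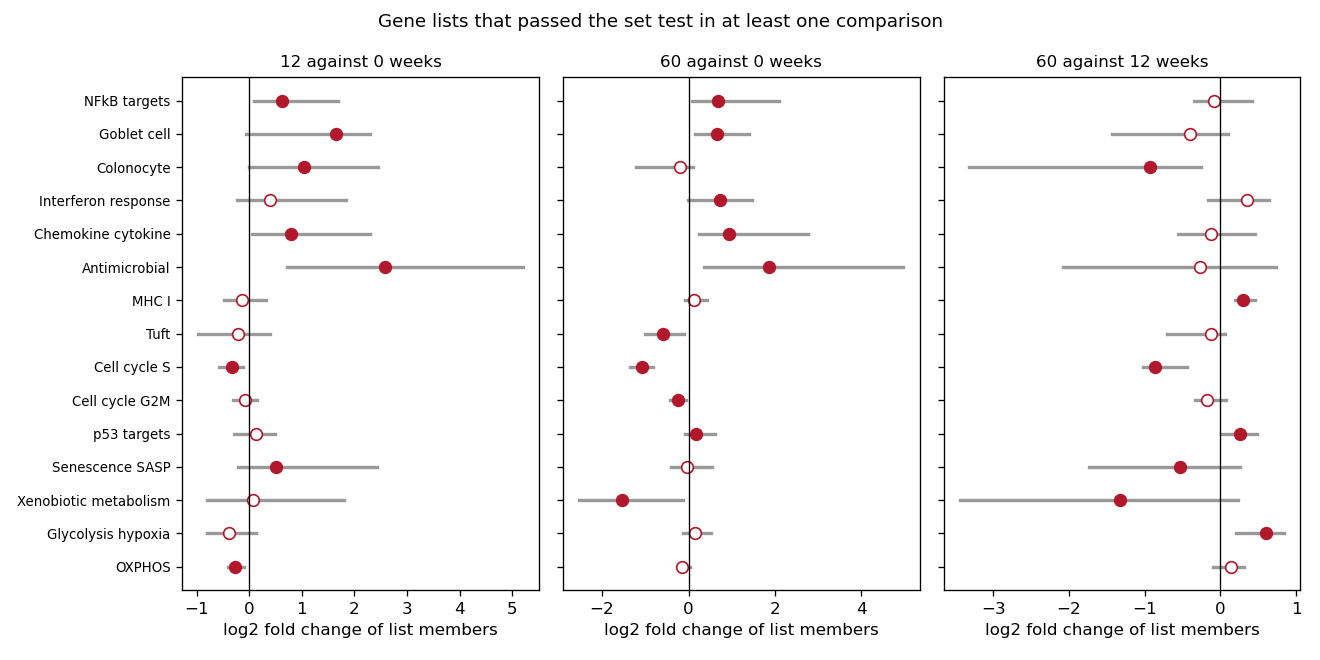
Median log2 fold change of the measured members (points) with the quartiles (bars) for 15 gene lists in the 3 comparisons, where filled points have an adjusted p under 0.05 by camera with the preset correlation. NF-kB targets lie at 0.62 and 0.68 against 0 weeks and at -0.09 between 60 and 12 weeks, and DNA replication genes at -0.32, -1.08 and -0.86.

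The comparison of 60 with 0 weeks asks what stood changed after the long treatment. At 60 weeks, 20 of 34 NF-kB targets, 16 of 30 chemokine and cytokine genes and 12 of 21 defence genes were higher and 40 of 46 DNA replication genes lower, and each list call ended with an estimated correlation (adjusted p = 0.597). Itln1 was at least 3022-fold higher, Nts at least 2551-fold and S100a9 at least 125-fold. E2f1, a transcription factor of the G1/S transition, fell by 1.65 ± 0.12 (adjusted p = 3.75e-05), and Rrm2, a subunit of ribonucleotide reductase, fell by 1.19 ± 0.10 (adjusted p = 6.23e-05). The Y-linked gene Ddx3y, at 1.14 ± 0.08 at 0 weeks, was at background on all 3 arrays of 60 weeks and at least 58.2-fold lower. Uty, another Y-linked gene, chosen after its values were seen, was also at background on these arrays.

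Of the 34 NF-kB targets, 20 rose and 0 fell at 60 weeks (20 adjusted over the list alone), with a median of 0.68, or 0.67 with members at their bound (adjusted p = 1.54e-06, and 0.597 with an estimated correlation). Cxcl5 rose by 5.71 ± 0.23, the cytokine gene Tnf by 2.13 ± 0.13 and Zc3h12a, which degrades inflammatory transcripts, by 2.67 ± 0.20, and Cxcl2 was at least 7.10-fold higher. Nfkbia, Tnfaip3, Cxcl1 and Lcn2 rose by 0.99 ± 0.15, 1.63 ± 0.18, 2.03 ± 0.29 and 4.97 ± 0.51. Of the 30 chemokines and cytokines 16 rose and 2 fell (18 adjusted over the list alone), with a median of 0.94, or 0.65 with members at their bound (adjusted p = 5.29e-06, and 0.597 with an estimated correlation). Csf2 and Ccl5 rose by 6.70 ± 0.34 and 2.80 ± 0.14, and Cxcl3 was at least 16.9-fold higher. Of the 21 defence genes 12 rose and 2 fell (15 adjusted over the list alone), with a median of 1.85, or 0.80 with members at their bound (adjusted p = 9.38e-05, and 0.597 with an estimated correlation). Duoxa2 was at least 238-fold and Reg3g at least 5.78-fold higher.

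Interferon-stimulated genes passed at 60 weeks, with 11 of 38 up and 1 down (17 adjusted over the list alone) and a median of 0.73 (adjusted p = 0.00607, and 0.902 with an estimated correlation). The antiviral genes Oas1a, Oas3 and Oasl1 rose by 6.44 ± 0.50, 3.32 ± 0.64 and 1.56 ± 0.16, and Rsad2 was at least 2.09-fold higher. Oas3 was above background on only 1 of 3 arrays at 0 weeks. With the row of the slide as a block, in which 60 and 0 weeks share no row, the call of Oas3 ended (4.59, adjusted p = 0.0696). The call ended without the shifted chromosomes (0.46, adjusted p = 0.0975; range over its alternatives 4.24e-06 to 0.902). Of 17 goblet cell markers 9 rose and 2 fell (12 adjusted over the list alone), with a median of 0.66, or 0.60 with members at their bound (adjusted p = 0.00841, and 0.597 with an estimated correlation); Muc13, Creb3l4 and Ang4 rose by 3.96 ± 0.20, 2.42 ± 0.13 and 0.66 ± 0.11, and Sytl2 was at least 1.24-fold higher. The row block ended the call of Ang4 (0.66, adjusted p = 0.0769). Colonocyte markers had 4 up and 6 down of 31 (10 adjusted over the list alone) with a median of -0.20 and no call (adjusted p = 0.421); Emp1 fell by 1.13 ± 0.10 and Ceacam20 rose by 2.70 ± 0.28. Krt20 (-1.31 ± 0.57, adjusted p = 0.112) and Car1 (-2.73 ± 1.16, 0.107) did not pass, and both passed without replicate 2 of 12 weeks (adjusted p = 0.000761 and 0.00518) and with only the 2 groups compared (0.000784 and 0.00748). Stem cell markers had 4 up and 1 down of 22 (5 adjusted over the list alone) with a median of 0.06 (adjusted p = 0.607). Noxa1, Prom1 and Lrig1 rose by 1.98 ± 0.28, 0.90 ± 0.14 and 0.82 ± 0.18. Slc12a2 rose by 0.54 ± 0.13 (adjusted p = 0.0148), a call that ended without replicate 2 or 3 of 0 weeks (0.0503 and 0.0571), and Lgr5 lay at 0.74 ± 0.65 (adjusted p = 0.417). With the row block the calls of Noxa1, Lrig1 and Slc12a2 ended, at 1.30, 0.41 and 0.46 (adjusted p = 0.157, 0.464 and 0.298). Lgr5 passed with only the 2 groups compared (0.74, adjusted p = 0.0172) and lay at -1.55 with the row block (0.235). The row block value takes in the difference of replicate 1 of 12 weeks (-1.72) from replicates 2 and 3 of 12 weeks (1.43 and -0.13). Its sign therefore does not show a dependence on the row.

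Of 46 DNA replication genes, 1 rose and 40 fell at 60 weeks (43 adjusted over the list alone), with a median of -1.08 (adjusted p = 2.71e-17, and 0.597 with an estimated correlation). Cdc45, of the replicative helicase, and the DNA ligase gene Lig1 changed by -1.34 ± 0.11 and -1.27 ± 0.11. Of 52 mitotic genes 2 rose and 15 fell (17 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.0125, and 0.953 with an estimated correlation). Nuf2, Cks1b, Ect2 and Hmgb2 changed by -0.97 ± 0.14, -0.65 ± 0.10, -0.64 ± 0.11 and -0.93 ± 0.16. The mitotic list's call ended without replicate 2 of 0 weeks (-0.20, adjusted p = 0.0537) or replicate 1 of 60 weeks (-0.17, 0.0795), and the calls of Cks1b and Ect2 with median centring (adjusted p = 0.0622 and 0.0640) and that of Hmgb2 with the row block (-1.11, 0.0525). Mki67 (-0.31 ± 0.17, adjusted p = 0.204), Cdkn1a (-0.09 ± 0.16, 0.696, with its other probe at -0.84), Cdkn2a (0.11 ± 0.15, 0.615, at background in both groups), Myc (0.20 ± 0.18, 0.419), Ly6a (0.26 ± 0.15, 0.228) and Epcam (-0.06 ± 0.12, 0.710) did not pass. Cdkn1a passed with the mean over its probes (-0.47, adjusted p = 0.0158). Ly6a passed without replicate 2 of 12 weeks (0.26, adjusted p = 0.0217) and with only the 2 groups compared (0.0351), and Cdh1 rose by 0.34 ± 0.10 (adjusted p = 0.0303), a call that ended in 8 of 25 alternatives, among them without replicates 2 or 3 of 0 weeks (0.0921 and 0.109) and replicates 1 or 2 of 60 weeks (0.0636 and 0.0905).

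Of 36 p53 targets 15 rose and 1 fell (16 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.00809, and 0.664 with an estimated correlation). Plk3, Fas, Mdm2 and Sesn2 rose by 0.87 ± 0.09, 1.33 ± 0.15, 0.90 ± 0.12 and 0.85 ± 0.13. The call ended without the shifted chromosomes (0.07, adjusted p = 0.0987) and with the row of the slide as a block (0.13, 0.140), which also ended that of Mdm2 (0.89, adjusted p = 0.0528). Of 30 xenobiotic metabolism genes 2 rose and 16 fell (20 adjusted over the list alone), with a median of -1.53, or -1.34 with members at their bound (adjusted p = 0.00465, and 0.611 with an estimated correlation). The sulfotransferase gene Sult1c2, the glucuronosyltransferase gene Ugt2b34 and Cyp3a13 changed by -5.63 ± 0.44, -3.64 ± 0.33 and -2.03 ± 0.21, while Cyp2b10 rose by 4.64 ± 0.17. Of 15 tuft cell markers 0 rose and 7 fell (7 adjusted over the list alone), with a median of -0.60 (adjusted p = 0.0117, and 0.597 with an estimated correlation), or -0.38 without replicate 3 of 0 weeks. Alox5ap, Cd24a and Dclk1 changed by -2.55 ± 0.14, -1.34 ± 0.12 and -1.05 ± 0.15, and Il17rb was at least 2.07-fold lower, a call that ended with the row block (-2.30, adjusted p = 0.0888). Without the shifted chromosomes the xenobiotic (-0.90, adjusted p = 0.201) and tuft cell (-0.23, 0.430) calls ended.

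Further large rises at 60 weeks were those of Slc16a3 (10.25 ± 0.30), Prl2a1 (at least 281-fold), Il1f6, a cytokine of the interleukin-1 family (at least 173-fold), Tdrp (at least 57.7-fold), Psors1c2 (6.81 ± 0.93) and P2rx7, an ATP-gated channel (6.78 ± 0.36, and 3.88 and 4.36 by its other probes). Psors1c2 and P2rx7 were above background on only 1 of 3 arrays at 0 weeks, so the size of their change rests on background readings. Gpc1, Syce2, Tmprss11c, Map2k6, Ctsc, Gramd1a and Fam149a were at background on every 60 weeks array and at least 205-fold, 130-fold, 89.3-fold, 68.0-fold, 63.2-fold, 56.5-fold and 42.8-fold lower. Serpinb7 and Akr1c18 changed by -9.01 ± 0.73 and -8.01 ± 0.99. The calls of Psors1c2 and Akr1c18 ended with the row block, at 4.77 and -6.52 (adjusted p = 0.118 and 0.0656). In all, 4597 genes (32.8%) were called, 2339 higher and 2258 lower, and 1625 by at least 2-fold. The groups did not overlap for 7915 genes (56.5%, against 10% by chance). With the row of the slide as a block, which links the 60 and 0 weeks arrays only through those of 12 weeks, 1389 genes were called. With arrays centred on their median, which moves the median change of all genes from -0.04 to 0.08, 3045 were called, 2007 higher and 1038 lower.

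**Figure D2:**
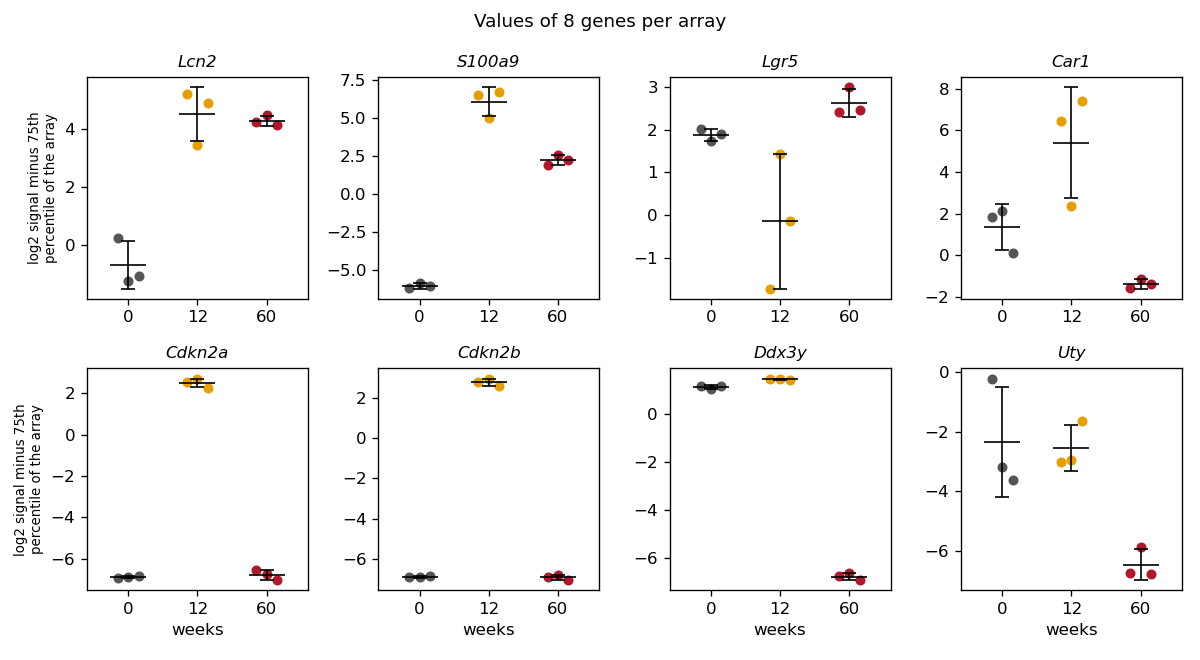
Log2 signal relative to the array's 75th percentile of 8 genes on each of the 9 arrays (points), with the mean and SD of each group (bars). Lcn2 and S100a9 lie higher at 12 and 60 weeks than at 0 weeks, Cdkn2a and Cdkn2b stand above background only at 12 weeks, Cdkn2b at 2.79, and Ddx3y and Uty at background at 60 weeks.

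The comparison of 60 with 12 weeks asks what changed between the treatment periods. Cdkn2b and Cdkn2a, high at 12 weeks, were at background at 60 weeks and at least 183-fold and 149-fold lower. The differentiation marker Krt20 fell by 3.29 ± 0.57 (adjusted p = 0.00316), Car1 fell by 6.76 ± 1.16 (adjusted p = 0.00309), and Lgr5 rose by 2.75 ± 0.65 (adjusted p = 0.0121) to 2.62 ± 0.32.

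Of 31 colonocyte markers 2 rose and 17 fell (21 adjusted over the list alone), with a median of -0.93 (adjusted p = 0.000365, and 0.597 with an estimated correlation). Slc5a8 was at least 63.0-fold lower, Ugt2b34 and Cyp3a13 changed by -3.76 ± 0.33 and -2.45 ± 0.21, and B4galnt2 rose by 5.17 ± 0.34 from a level above background on only 1 of 3 arrays. The median was -1.45 without replicate 2 of 12 weeks, and the call ended with the deposited value table (-0.38, adjusted p = 0.289; range over its alternatives 1.17e-06 to 0.597). DNA replication genes fell further, with 0 up and 36 down of 46 (38 adjusted over the list alone) and a median of -0.86 (adjusted p = 2.66e-12, and 0.597 with an estimated correlation). Pole, the catalytic subunit of DNA polymerase epsilon, fell by 1.48 ± 0.13, and E2f1 and Cdc45 changed by -1.33 ± 0.12 and -1.10 ± 0.11. Of 36 glycolysis and hypoxia genes 18 rose and 0 fell (18 adjusted over the list alone), with a median of 0.61 (adjusted p = 0.00147, and 0.818 with an estimated correlation). For these genes replicate 2 of 12 weeks deviated from replicates 1 and 3 by a median of 0.35 (percentile 100 of random lists of like level). P4ha1, P4ha2, Pfkl and Hk1 rose by 1.81 ± 0.30, 1.10 ± 0.21, 0.68 ± 0.12 and 0.74 ± 0.15. Against 0 weeks this list had a median of -0.38 at 12 weeks and 0.15 at 60 weeks, with no call (adjusted p = 0.382 and 0.0851). P4ha1 and Hk1 at 60 weeks overlapped their 0 weeks values, while P4ha2 and Pfkl lay above theirs. The rise was thus in part a return from lower levels at 12 weeks.

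Of 30 xenobiotic metabolism genes 4 rose and 17 fell (25 adjusted over the list alone), with a median of -1.32 (adjusted p = 0.00395, and 0.611 with an estimated correlation). Replicate 2 of 12 weeks already deviated from replicates 1 and 3 by a median of -1.08 for these genes (percentile 0 of random lists of like level). Sult1b1 fell by 3.63 ± 0.37 and Ahrr was at least 3.75-fold lower. The call ended with the deposited value table (-0.25, adjusted p = 0.423) and without the shifted chromosomes (-0.84, 0.201). Of 28 senescence and secretory genes 2 rose and 11 fell (15 adjusted over the list alone), with a median of -0.53, or -0.47 with members at their bound (adjusted p = 0.0105, and 0.597 with an estimated correlation). Serpinb2 fell by 3.53 ± 0.29, and Igfbp7 was at least 1.33-fold lower, a call that ended with normexp (-0.28, adjusted p = 0.143). The list's call ended with probes above background on all 9 arrays (-0.27, adjusted p = 0.536), with the deposited value table (-0.32, 0.106), without genes of other lists (-0.53, 0.0710) and without the shifted chromosomes (-0.40, 0.347). Of 20 genes of MHC class I presentation 9 rose and 0 fell (11 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0213, and 0.597 with an estimated correlation). H2-T10, Tap1 and Psmb8 rose by 0.93 ± 0.16, 0.89 ± 0.20 and 0.85 ± 0.20, and H2-T23 by 0.42 ± 0.09, a call that ended with quantile normalization (0.17, adjusted p = 0.281), and that of Tap1 ended with the row block (0.80, 0.0660). H2-T10 and H2-T23 at 60 weeks overlapped their 0 weeks values, while Tap1 and Psmb8 lay above theirs. Against 0 weeks the MHC class I list had a median of -0.14 at 12 weeks and 0.12 at 60 weeks, with no call (adjusted p = 0.871 and 0.134). The list's call ended with quantile normalization (0.16, adjusted p = 0.123), the deposited value table (0.24, 0.181) and without replicate 2 of 12 weeks (0.28, 0.0580). Of 36 p53 targets 14 rose and 1 fell (16 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.0498, and 0.754 with an estimated correlation), and Xpc, Sesn1 and Polk rose by 0.78 ± 0.12, 0.93 ± 0.15 and 0.47 ± 0.11 and Psrc1 from 3.36 ± 0.33 to 4.56 ± 0.03. That call ended in 14 of 27 alternatives (adjusted p 0.0104 to 0.754), among them without replicate 1 of 12 weeks (0.0606), replicate 3 of 12 weeks, or replicate 1 or 2 of 60 weeks (0.0538 and 0.0694). At 12 against 0 weeks the p53 targets had a median of 0.13 and no call (adjusted p = 0.492). Xpc and Psrc1 at 60 weeks overlapped their 0 weeks values, while Sesn1 and Polk lay above theirs.

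NF-kB targets had 8 up and 6 down of 34 (15 adjusted over the list alone) and a median of -0.09 with no call (adjusted p = 0.829). Nfkb2 and Birc2 rose by 0.81 ± 0.09 and 0.72 ± 0.08, and Ptgs2 and Ccl2 changed by -1.28 ± 0.16 and -3.96 ± 0.51. Nfkbia (-0.01 ± 0.15, adjusted p = 0.971), Tnfaip3 (-0.11 ± 0.18, 0.678), Cxcl1 (-0.35 ± 0.29, 0.374) and Lcn2 (-0.23 ± 0.51, 0.747) did not pass, while Reg3g rose by 1.68 ± 0.36. Interferon-stimulated genes had 5 up and 2 down of 38 (5 adjusted over the list alone) and a median of 0.35 (adjusted p = 0.351), which passed without replicate 1 of 12 weeks (0.56, adjusted p = 0.0390) and was 0.01 without replicate 2. Oasl1, Isg20, Dhx58 and Stat2 rose by 1.31 ± 0.16, 1.35 ± 0.20, 1.97 ± 0.30 and 0.85 ± 0.17. Goblet cell markers had 4 up and 5 down of 17 (9 adjusted over the list alone) and a median of -0.40 (adjusted p = 0.382), with called changes of -2.04 ± 0.18 for Sytl2, -1.45 ± 0.15 for Galnt12, 0.74 ± 0.11 for Ang4 and 0.79 ± 0.13 for Creb3l4. Stem cell markers had 2 up and 3 down of 22 (5 adjusted over the list alone), with a median of 0.13 but a mean of -0.28 and a downward test (adjusted p = 0.607). Ascl2 was at least 5.73-fold lower, and Clca4b and Tert changed by -4.29 ± 0.55 and -1.15 ± 0.17. The panel genes Ly6a (0.42 ± 0.15, adjusted p = 0.0606), Mki67 (-0.28 ± 0.17, 0.227), Cdkn1a (0.12 ± 0.16, 0.560, with its other probe at -0.74 and called), Myc (-0.04 ± 0.18, 0.895), Cdh1 (0.07 ± 0.10, 0.613) and Epcam (0.22 ± 0.12, 0.179) did not pass. Ly6a passed without replicate 2 of 12 weeks (0.61, adjusted p = 0.000687) and with limma's trended and robust variance (0.0365), and Epcam without replicate 2 of 60 weeks (0.33, 0.0479).

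Among the largest rises from 12 to 60 weeks, the homeobox genes Hoxc6, Isl2 and Hoxd10 were at background at 12 weeks and at least 31.5-fold, 20.5-fold and 6.15-fold higher at 60 weeks, and Meis2 rose by 4.93 ± 0.31. Khdc1a and Adgra1 were at least 16.1-fold and 9.22-fold higher, and Insl6, Gzmm and Pf4 rose by 4.26 ± 0.39, 4.24 ± 0.21 and 4.12 ± 0.28. Besides Cdkn2a and Cdkn2b, the genes Fam149a, B4galt4, Syce2, Ctsc, Rtl8b, Rtl8c, Bche and Ddx3y were at background at 60 weeks and at least 153-fold, 144-fold, 112-fold, 108-fold, 88.1-fold, 84.2-fold, 80.4-fold and 72.5-fold lower than at 12 weeks. In all, 5373 genes (38.3%) were called, 2900 higher and 2473 lower, and 1777 by at least 2-fold, 791 higher and 986 lower. The groups did not overlap for 6621 genes (47.2%, against 10% by chance). Centring on the median moved the median change of all genes from 0.02 to 0.16 and called 4019 genes, 2742 higher and 1277 lower, while the percentile over bright probes gave 2531 higher and 2892 lower and quantile normalization 2599 and 2765, and 3463 were called with the row of the slide as a block.

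Whether the changes at 12 and 60 weeks fell on the same genes was asked against the shared 0 weeks arrays. Of the called genes, 1217 were higher and 1191 lower at both times, while 132 were higher at 12 and lower at 60 weeks and 122 the reverse. In 20 simulations that shuffled the changes of each comparison among genes of like level and kept the 0 weeks arrays shared, a test added after the data were seen, a mean of 705 and 845 genes were shared (highest 734 and 888). The log2 fold changes of both comparisons correlated at 0.55 across genes, against 0.02 with the shuffled changes (highest 0.04) and 0.51 in simulated arrays without group differences (highest 0.54). The same sign was seen for 67.7% of genes, against 51.9% and 66.5%, and the covariance was 0.601, against 0.0241 and 0.0306. The 3 arrays of 0 weeks cannot be split between the comparisons, so part of the shared calls may stem from them. With the row of the slide as a block 939 genes were shared, against 2408.

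Markers of other cell types did not pass in any comparison. At 12 against 0 weeks the medians were 0.01 for 8 fibroblast genes, -0.20 (-0.11 with members at their bound) for 11 leukocyte genes, 0.04 for 8 endothelial genes and -0.32 for 8 muscle and glia genes (adjusted p = 0.829, 0.879, 0.946 and 0.871). At 60 against 0 weeks they were -0.10, -0.32, -0.11 and 0.18 (adjusted p = 0.659, 0.615, 0.946 and 0.382), and at 60 against 12 weeks -1.32 (-0.57 with members at their bound), 0.03, 0.13 and 0.14 (adjusted p = 0.253, 0.871, 0.905 and 0.216).

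Genes of some chromosomes stood higher as a whole, a pattern noticed after the data were seen. Over 12209 genes above background on all arrays, the median change at 12 weeks exceeded that of the unshifted chromosomes by 0.37 on chromosome 4, 0.29 on chromosome 5, 0.34 on chromosome 12 and 0.29 on chromosome 14. At 60 weeks the excess was 0.31, 0.23, 0.34 and 0.24 on these, and 0.40 on chromosome 10 and 0.49 on chromosome 19, which lay at 0.04 and 0.09 at 12 weeks. The other chromosomes lay between -0.10 and 0.10. Without these chromosomes and Y, an alternative chosen after seeing the data, 1538 genes were higher and 2574 lower at 12 against 0 weeks, 1116 and 1864 at 60 against 0 weeks and 1869 and 1821 at 60 against 12 weeks. The arrays were not scaled anew for this. The median change of the remaining genes was -0.117 and -0.115 at 12 and 60 against 0 weeks, against -0.057 and -0.042 for all genes. Part of the excess of falls may stem from this offset, and list medians in this alternative carry it too.

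**Figure D3:**
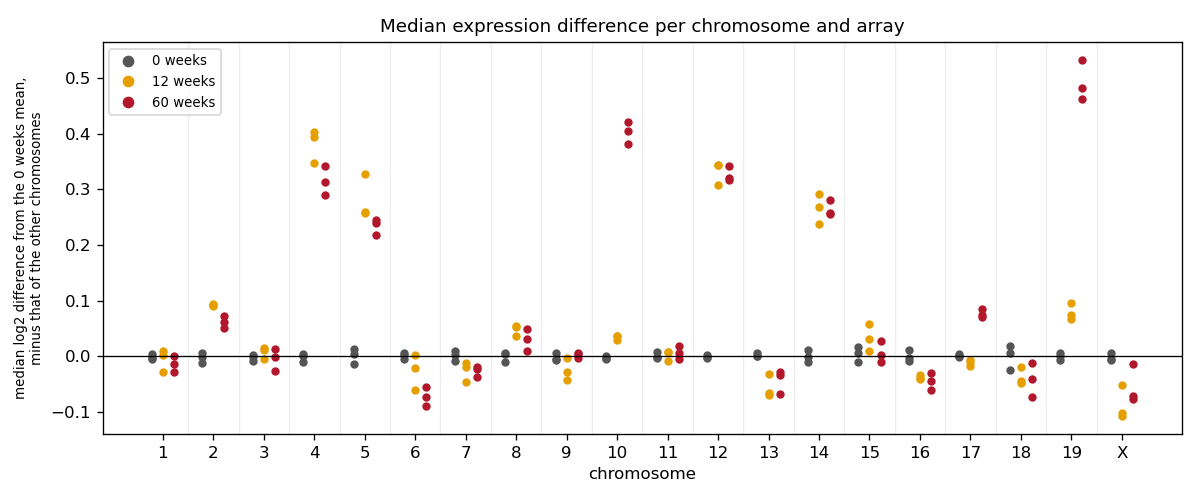
Median log2 difference from the 0 weeks mean of the genes of each chromosome on each array, minus that of the unshifted chromosomes. Chromosomes 4, 5, 12 and 14 lie higher on the 12 and 60 weeks arrays, and chromosomes 10 and 19 only on those of 60 weeks, and each array of a shifted group lies at 0.22 or above.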

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

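The inclusion of features without a gene symbol was chosen only after the data were seen. Against the same 0 weeks arrays, the changes at 12 and 60 weeks differed, by camera's test of 60 against 12 weeks, for 7 of the gene lists. The change at 60 weeks minus that at 12 weeks had a median of -0.93 for colonocyte markers, -0.86 for DNA replication genes, -0.53 for senescence and secretory genes and -1.32 for xenobiotic metabolism genes. It was 0.30 for MHC class I presentation, 0.26 for p53 targets and 0.61 for glycolysis and hypoxia genes. None of these list calls holds with an estimated correlation (adjusted p 0.597 to 0.818).

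Signal also appeared in features without a gene symbol, which the comparisons leave out. Of 8362 such features above background, 672 were called higher and 1886 lower at 12 than at 0 weeks, and 718 higher and 928 lower at 60 than at 0 weeks. At 60 against 12 weeks 1384 were higher and 678 lower.

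The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. At 12 against 0 weeks the real split called 5852 genes and 1 of 10 splits, the real one, reached that number, with 0 genes in the highest other. At 60 against 0 weeks the real split called 4597 and the highest other 0, and at 60 against 12 weeks 5373 and 2. For the F test among the 3 groups, 1 of 100 drawn splits, the real one, reached 7944 genes and the highest other called 1886. A random division of independent arrays would thus rarely give that count. The labels do not say whether replicates are separate cultures, so differences between single cultures are not excluded by it.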

How the results depend on the processing

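Of the 28 alternatives, 2 were chosen after seeing the data (features without a symbol included, and the shifted chromosomes left out). No result turned its direction while called. Of 189 called results for named genes, 169 kept their call under every alternative that gave a value. Outside the fixed panel, these genes were named for large changes or low adjusted p in the same data. This share therefore does not describe all called genes. Apart from the estimated correlation, with which no list call held, 4 of 7 called results of the 5 main lists (NF-kB, stem cell, goblet cell, colonocyte, interferon) and 6 of 18 of the other lists kept their call. The estimate was -0.034 for goblet cell markers, below the preset 0.01, and 0.012 for senescence and secretory genes, near it. A higher correlation among their own members therefore does not by itself explain why the calls of these lists ended. Where no cause is named, the cause was not tested.

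The number of genes called at 60 against 0 weeks was 3045 with median centring, 1389 with the row of the slide as a block and 2980 without the shifted chromosomes, which leaves fewer genes to test. With the row as a block it was 3463 at 60 against 12 weeks. Requiring a 2-fold change gave 2070, 1625 and 1777 genes at 12 against 0, 60 against 0 and 60 against 12 weeks. Genes shared by the comparisons against 0 weeks numbered 1416, 939 and 834 with median centring, the row block and the 2-fold requirement. A block for the replicate numbers gave 5792, 4453 and 5245 genes. Residuals of equal numbers correlated at -0.0816 to 0.202. They reached 0.197 for replicate 3 of 0 and 12 weeks and 0.202 for replicate 2 of 0 and 60 weeks, and the other pairs lay at 0.0921 or lower.

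Interferon-stimulated genes at 12 against 0 weeks passed without a filter on dim probes and with features without a symbol (0.39 in each) and with the row as a block (0.95), and at 60 against 12 weeks with the row as a block (0.60). Their 60 against 0 weeks call ended without the shifted chromosomes (0.46). Colonocyte markers lost their call with the deposited value table at 12 against 0 weeks (0.21) and at 60 against 12 weeks (-0.38), and without shared genes at 12 against 0 weeks (1.80). At 60 against 0 weeks they lay at -0.13 without the shifted chromosomes. NF-kB targets at 60 against 12 weeks lay at -0.0441 with the deposited table and 0.0304 with the row block, and stem cell markers at 60 against 0 weeks at -0.0818 with the row block. With an estimated correlation the calls ended at unchanged medians: at 12 against 0 weeks 0.62 for NF-kB, 1.66 for goblet cell and 1.04 for colonocyte markers, at 60 against 0 weeks 0.68 for NF-kB, 0.66 for goblet cell and 0.73 for interferon genes, and at 60 against 12 weeks -0.93 for colonocyte markers.

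Leaving out each array in turn gave medians of 0.12 to 0.73 for interferon genes at 12 against 0 weeks, 0.00883 to 0.564 for these at 60 against 12 weeks, -0.230 to 0.0362 for NF-kB targets at 60 against 12 weeks and -1.45 to -0.72 for colonocyte markers at 60 against 12 weeks. The gene counts ranged from 4221 to 7394, 3196 to 6018 and 3622 to 7061, each highest without replicate 2 of 12 weeks. Genes near background are limited by signal over the negative controls, 99.3 to 150 at the 75th percentile.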

Other observations

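The tests of the slide row, of mixed RNA, of dimmer arrays and of Xist, the chromosome pattern itself, the use of goblet cell markers and of spot variation in weighing replicate 2 of 12 weeks, the tally of Y-linked genes, and the genes Uty and Mtap were chosen only after the data were seen. Many genes called at 12 against 0 weeks were called in the other direction at 60 against 12 weeks: 1554 were called lower at 12 than at 0 weeks and higher at 60 than at 12 weeks, and 1285 the reverse. Of these, 1227 and 934 were not called at 60 against 0 weeks, and the others still differed from 0 weeks. The homeobox gene Hoxc6 went from -0.48 ± 0.09 at 0 weeks to -5.37 ± 0.54 and back to 0.19 ± 0.03 (mean ± SD, n = 3), and the protease gene Gzmm from 4.77 ± 0.16 to -0.57 ± 0.44 and 3.67 ± 0.12. The reverse held for Rtl8b and Rtl8c, derived from a retrotransposon, at 1.74 ± 0.20 and 1.68 ± 0.18 at 12 weeks and at background at 0 and 60 weeks. The noise of the 12 weeks arrays enters both comparisons with opposite sign: their changes correlated at -0.56 across genes, against -0.49 in simulated arrays without group differences and -0.74 with the fitted changes shuffled among genes of like level. The shuffling also removes what the changes at 12 and 60 weeks share, so this correlation cannot decide whether reversals are in excess. The counts of genes called in opposite directions were not simulated.

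Some further lists did not pass. MHC class II genes (7 measured) had medians of 1.35 at 12 and 1.99 at 60 against 0 weeks, or 0.74 and 0.66 with members at their bound (camera, adjusted p = 0.253 and 0.0776; at 60 weeks 0.0263 to 0.597 over the alternatives). Of 30 TGF-beta and BMP targets, 5 rose and 11 fell at 60 against 0 weeks and 6 rose and 12 fell at 60 against 12 weeks, with medians of -0.32 and -0.27 (adjusted p = 0.0714 and 0.0707). They passed in 5 and 4 of 27 alternatives (0.00694 to 0.597 and 0.0126 to 0.941). Of 44 fetal-like and regenerative epithelial genes 15 rose and 10 fell at 12 weeks and 17 rose and 8 fell at 60 weeks (adjusted p = 0.382 and 0.218).

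Genes of chromosomes 4, 5, 12 and 14 stood higher as a whole at 12 and 60 weeks, and those of 10 and 19 at 60 weeks. The tables argue against a bias with expression level, since 10 of 10 shifts lay above all of 10000 lists of genes matched on level. They argue against the row of the slide, since the 12 weeks array in the row of the 0 weeks arrays showed shifts of 0.24 or more on chromosomes 4, 5, 12 and 14, while chromosomes 10 and 19 lay at 0.07 or less on the 12 weeks arrays in the row of 60 weeks replicates 1 and 2, and against a few regions, since 100% of 50 segments, 5 in gene order per shifted chromosome and comparison, lay over 0.1 above the unshifted chromosomes (0.18 to 0.59). A candidate explanation is an extra copy of whole chromosomes in cultures with 2 copies: the highest shift, 0.49, stays below 0.58, the log2 of 1.5 that an extra copy in every cell could give. DNA was not analysed here, and whether treatment, time in culture or the choice of culture lies behind the pattern stays open.

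Replicate 2 of 12 weeks stood apart from replicates 1 and 3. RNA of the other groups mixed in is argued against as the only cause, since 34.0% of 53 genes above background only at 12 weeks were at or above replicates 1 and 3 in replicate 2, where mixing would lower nearly all, although their median deviation was -0.33 (lower quartile -1.40). Noise of dim spots alone is argued against, since among the brightest genes replicate 2 differed from replicate 1 by 2.31 times the difference between replicates 1 and 3. The scanner software's median variation between spots of a probe was 4.40%, within the 3.50% to 4.90% of the other arrays. Neither value can show a difference in RNA or labelling quality, so a poorer sample or array stays open. Signal over negative controls (99.3, against 105 on the next array) and the share of probes above background (49.2%, against 49.5%) were the lowest. A hypothesis of fewer differentiated and more stem-like cells in this sample stays open: colonocyte markers deviated by -0.89, at percentile 0 of matched random lists, and stem cell markers by 0.39, at percentile 99.9, but goblet cell and deep crypt secretory markers also lay higher, by 0.39 and 0.78, where fewer differentiated cells of all kinds would lower them. Antimicrobial, interferon and NF-kB genes deviated too, by -0.88, -0.80 and -0.38, but xenobiotic metabolism genes by -1.08, cholesterol synthesis genes by 0.82, mitotic genes by 0.41 and glycolysis genes by 0.35, which a weaker response alone does not cover, and no biological explanation of the design was tested, since replicates share their group.

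Of the genes above background at 12 weeks, 236 were at background on all 60 weeks arrays. Of the 236, 71 were above background at 0 weeks too, and 129, among them Cdkn2a and Cdkn2b, were at background on all 0 weeks arrays. Dimmer 60 weeks arrays are argued against, since 33 of the 236 genes lay above the 75th percentile at 12 weeks. Loss of stretches of DNA stays open: neighbouring pairs, among them Cdkn2a with Cdkn2b and Ddx3y with Uty, numbered 15 against 3.94 expected, at percentile 100 of random draws, but genes off at 0 and on at 60 weeks also paired 12 times against 2.45 expected, so shared regulation could give such pairs. Mtap next to Cdkn2a was still above background at 60 weeks, at 0.81 ± 0.31, but lower than at 0 weeks (1.48 ± 0.15) and 12 weeks (1.36 ± 0.13). Of 7 tested Y-linked genes, 6, among them Ddx3y and Uty, were at background on all 60 weeks arrays, but only 3 were above background on all 12 weeks arrays and 2 on all 0 weeks arrays, and samples from a female animal stay open as well, since the 2 Xist probes gave 0 readings above background at 60 weeks but none on the other arrays either, and of 5 further probes of this transcript 1 was above background on 1 array of 0 and 1 of 12 weeks (-5.87 ± 1.62 and -5.79 ± 2.06, against -6.77 ± 0.20 at 60 weeks). These explanations cannot be told apart with the values at hand, and the treatment itself was not tested as a cause.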
